A study of Mus musculus with 9 samples.

How the data were processed

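RNA was measured on 1 expression microarray per sample in 9 samples of mouse CD8+ T cells specific for OVA, a model antigen, sorted by flow cytometry from the spleen at day 9 after infection with Listeria monocytogenes. Per the labels' protocols, 12 ng of total RNA per sample was amplified and labelled with biotin with NuGEN kits. The deposited values are log2 expression values per probe set, made by the authors with RMA, which corrects the background, quantile normalizes the probes across arrays and summarises each probe set, with Partek 6.5 also named, per the submitters' processing notes. The options of RMA and any filter are not given in the sources used here. RMA forces the probe intensities of all arrays onto one distribution, so a change shared by most transcripts would not be visible in these values, and small differences of bright genes are better measured than those of dim genes. The array medians lay between 5.97 and 6.05 on the log2 scale.

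The array table held 45037 probe sets. The platform annotation listed 29449 of them, of which 28898 had 1 gene and 551 several. The other 15588 are unnamed here. Symbols were updated through Entrez identifiers, which matched for 28689 probe sets, with the RefSeq gene table of assembly GRCm38.p6, used only for names and gene lengths. No genome build was named in the sources used here, so no coordinates are given. Each gene was represented by the probe set with the highest mean over all 9 arrays, which left 17097 genes, and probe sets with several genes were not used for genes.

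The 4 WT and 5 Tsc1-/- samples were grouped by the genotype in the labels. Each gene was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, with genotype as the only term, two-sided, and Benjamini-Hochberg adjustment over all 17097 genes. The threshold was an adjusted p under 0.05, with no filter on dim genes. All differences are Tsc1-/- minus WT on the log2 scale, and standard errors of single genes are limma's moderated ones. The sources say that samples came from WT or Tsc1-/- mice without saying whether each came from a separate animal, so the p-values measure the spread between these samples, and the number of arrays limits the precision.

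Gene lists, the genes always named and the tests were chosen before the data were examined. There were 37 lists with 588 gene entries, of which 504 were measured and 84 had no named probe set. The lists covered metabolism, mTOR signalling, effector and memory T cell genes, the cell cycle, stress responses, ribosomal proteins, receptors, and markers of other cells that a sort can let through. Lists of at least 5 measured genes, 36 in all, were tested with camera of limma with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The mean level of each list was also compared with an exact two-sided permutation test over the 126 splits of the 9 arrays into 4 and 5, adjusted over 37 lists, and the smallest p it can give is 0.00794. At equal macrophage marker level, a test chosen after the results were seen, the residuals of the list mean on the marker level were permuted (10000 orders, the real one included) and the t statistic of genotype compared. Camera asks whether a list moved more than other genes, while fry and the permutation test ask whether it moved at all.

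The genes named were Tsc1, then the 12 higher and 12 lower genes with the largest log2 difference among those past the threshold whose groups did not overlap and whose higher group mean was at or above 6.34, the median over genes, leaving out predicted genes. From each list, up to 4 members past the threshold with the smallest p were added, or up to 2 with the smallest p where none passed, of which some that did not pass are left out of the text. Klrg1, Tbx21, Eomes, Bcl2, Gzmb, Ifng, Foxo1, Cpt1a, Slc2a1, Hk2, Ldha, Myc and Hif1a were always given, and Il7r and Tcf7, also on that list, had no named probe set here. A further gene of that list is not reported here.

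The alternatives planned were the mean of a gene's probe sets, probe sets not joined to genes, dim genes left out, quantile normalization or median centring of the deposited values, a variance trend with robust estimation, array weights, the replicate number as a block, a fold minimum of 1.5, an adjusted p under 0.1, each array left out in turn, and the estimated correlation. After the data were seen, 4 were added: the macrophage marker level or the B cell marker level of each array as a covariate, removal of each array's trend on mean level and gene length (loess, span 0.3), and leaving out WT replicate 4 and Tsc1-/- replicate 1 together. Figures were drawn in Python 3.11.15.

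The gene and list tests were tested on simulated data with 17097 genes and 200 changed genes in the layout of Tsc1-/- against WT. The test recovered 63% of genes changed by 0.5 and 94% of those changed by 1 on the log2 scale, with 6 unchanged genes among 163 called. A simulated list of 20 genes shifted by 0.3 ranked 1 of 100 lists, and 0 of the 99 unshifted lists passed. Genes were drawn independently there, whereas the estimated correlation between genes of the real lists was 0.74 for mitosis and 0.69 for S phase. The simulation therefore does not check the list test on correlated genes.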

Results

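Expression was measured in OVA-specific CD8+ T cells from 4 WT samples, whose mice carried floxed Tsc1 alleles without cre, and from 5 Tsc1-/- samples, whose mice carried the same alleles with cre under Granzyme B. Tsc1 encodes a subunit of the complex that restrains mTORC1, the kinase that couples nutrients and growth signals to anabolic metabolism. Day 9 after Listeria monocytogenes infection lies near the end of expansion, when most responding cells are short-lived effectors and a minority are precursors of memory cells. The arrays were alike, with Pearson correlations of 0.987 to 0.991 within a genotype and 0.982 to 0.990 between genotypes over all probe sets. Xist was bright (11.42 in WT and 11.19 in Tsc1-/-) and the Y-linked gene Uty dim (3.91 and 3.97) in both groups.

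Tsc1 itself, measured first because it is the targeted gene, read 7.66 ± 0.09 (SD, n = 4) in WT and 7.40 ± 0.09 (SD, n = 5) in Tsc1-/- by its brightest probe set. Its level in Tsc1-/- was 83.3% of that in WT, a difference of -0.26 (SE 0.08). Every Tsc1-/- array lay below every WT array (exact permutation p = 0.00794, the smallest this design can give), while the adjusted p over all genes was 0.114 (limma), past the threshold only when dim genes were left out (adjusted p = 0.0483). A further Tsc1 probe set differed by -0.32 (exact permutation p = 0.0238) and the last by -0.01 (exact permutation p = 0.889). Where these probe sets lie relative to the floxed exons was not analysed here, so they check the labels only in part.

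**Figure D1:**
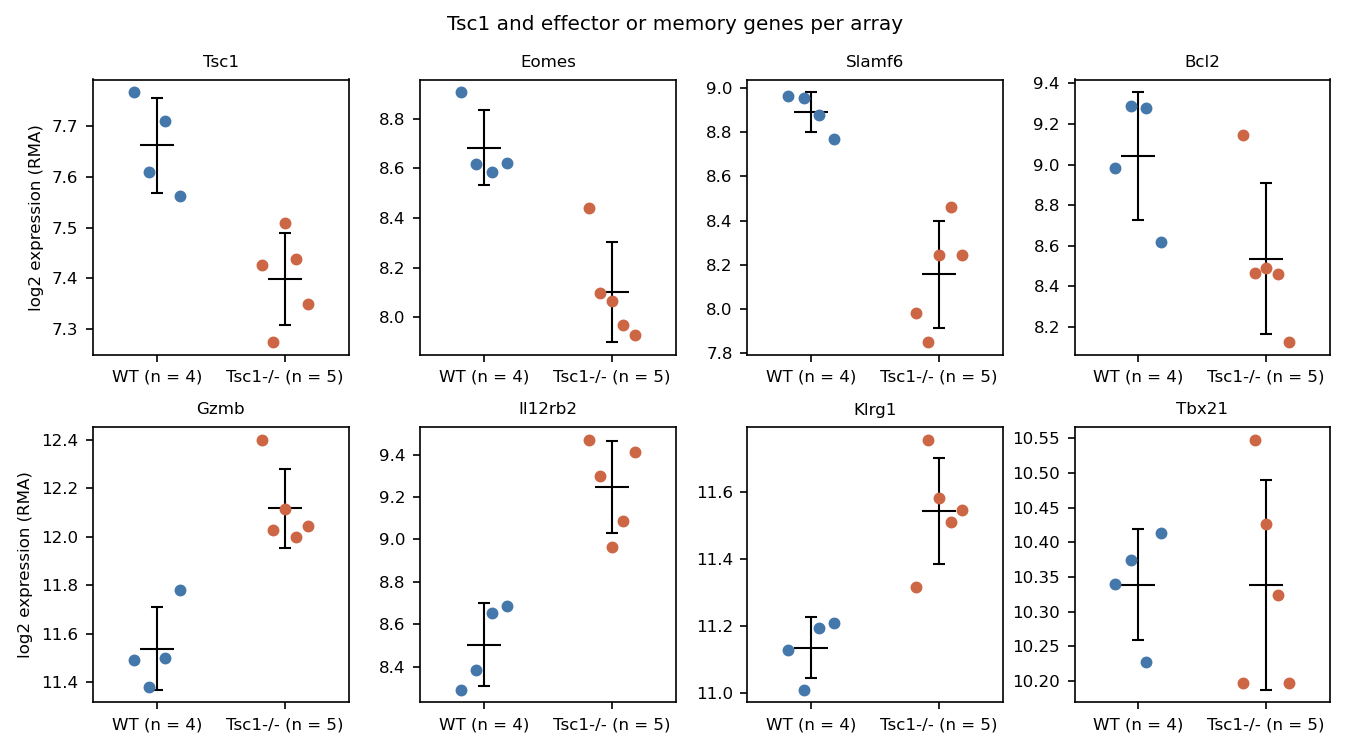
Log2 expression (RMA, vertical axes, which do not start at 0) of 8 genes on each array, for 4 WT and 5 Tsc1-/- samples. Each point is an array, the horizontal mark is the group mean and the error bar 1 SD. Tsc1, Eomes and Slamf6 were lower and Gzmb, Il12rb2 and Klrg1 higher on every Tsc1-/- array than on any WT array, while Bcl2 and Tbx21 overlapped.

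The comparison of the genotypes asks which effector, memory and metabolic genes depend on Tsc1 in responding CD8+ T cells. In Tsc1-/- cells, the gene lists of S phase, mitosis, sterol synthesis and the respiratory chain were higher on average, Gzmb and Il12rb2 rose, and the memory-associated genes Eomes and Slamf6 fell. These 4 genes kept their direction in all 23 other settings. They lost the threshold in 13 of them for Gzmb, 11 for Eomes, 7 for Il12rb2 and 7 for Slamf6. The 4 gene groups passed as lists (exact permutation, adjusted p = 0.0367 each; camera with its preset correlation), not with an estimated correlation (adjusted p = 0.0793 to 0.255), and of their members 3 of 18 (S phase), 7 of 19 (mitosis), 5 of 15 (sterol synthesis) and 2 of 27 (respiratory chain) rose by themselves. Of 17097 genes tested, 166 were higher and 53 lower in Tsc1-/- at an adjusted p under 0.05 (limma). The median difference was 0.49 for the higher and -0.51 for the lower genes, with 54 and 16 of them changed at least 1.5-fold. The genotypes did not overlap in 164 of the higher and 51 of the lower genes, and in 7.96% of all genes where chance gives 1.59%.

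The largest rise was that of AA467197, from 8.18 ± 0.34 (SD, n = 4) to 9.76 ± 0.26 (SD, n = 5), a difference of 1.57 (SE 0.16, adjusted p = 0.00612, limma). Gpx8, a peroxidase of the endoplasmic reticulum, rose by 1.47 (SE 0.25), and Serpinb1a, an inhibitor of neutrophil proteases, by 1.37 (SE 0.20). The metallothionein gene Mt1 rose by 1.14 (SE 0.20) and Lamp2, a protein of the lysosomal membrane, by 0.89 (SE 0.17). Of the other 7 genes in this ranking, 6 act in division: Depdc1a (1.15), Cdkn3 (1.02), Gmnn (0.93), which restrains replication licensing, Pbk (0.92), Pclaf (0.88), which binds PCNA, and Espl1 (0.88), the separase that cleaves cohesin. The last was Idi1, an enzyme of sterol synthesis, at 0.90. The adjusted p of these 12 genes was 0.0494 or lower.

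Among the lower genes, Ear3, of the eosinophil-associated ribonuclease family, fell by 2.14 (SE 0.42, adjusted p = 0.0363, limma) and Cd300ld, a receptor of myeloid cells, by 1.21 (SE 0.13, adjusted p = 0.00612, limma). The Ear3 probe set is of a type that can detect related transcripts. Ace, the angiotensin-converting enzyme, fell by 0.88 (SE 0.19). The receptor Slamf6 fell by 0.73 (SE 0.12), from 8.89 ± 0.09 to 8.16 ± 0.24 (SD, n = 4 and 5), and the T-box factor Eomes by 0.58 (SE 0.11), from 8.68 ± 0.15 to 8.10 ± 0.20. Gpr183, a receptor that guides lymphocyte positioning, fell by 0.62, the protease inhibitor genes Ctla2b and Ctla2a by 0.65 and 0.59, Lyst, needed for lytic granule formation, by 0.58, and Dgka, which limits diacylglycerol signalling, by 0.58. Kbtbd11 fell by 0.67 and Pou6f1 by 0.64. The adjusted p of these 12 genes was 0.0438 or lower. Of the genes with several probe sets, all probe sets differed in the called direction for 59 of 82 higher and 25 of 28 lower genes. Cyp51, Top2a, Cycs and Fads1, all of them higher by their brightest probe set, each had a further probe set with a difference under 0, at -0.05, -0.02, -0.08 and -0.04. The lowest probe sets of Ndufs8, Aldoc and Nusap1, also called higher, differed by only 0.007, 0.014 and 0.093.

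These counts changed with the arrays included. Without one array, the numbers of higher and lower genes were 1 and 1 (without WT replicate 1 and also without Tsc1-/- replicate 5), 2 and 1 (WT replicate 2), 70 and 13 (WT replicate 3), 297 and 159 (WT replicate 4), 6 and 2 (Tsc1-/- replicate 2), 41 and 12 (Tsc1-/- replicate 3), 21 and 9 (Tsc1-/- replicate 4) and 142 and 46 (Tsc1-/- replicate 1). All 166 and all 53 genes kept their direction in each. For the 164 and 51 whose genotypes did not overlap this was fixed beforehand. The higher genes were 75.8% of the calls as deposited, against 84.3% after median centring (338 higher, 63 lower), 55.8% after quantile normalization (43 higher, 34 lower) and 56.1% without the trend on level and gene length (55 higher, 43 lower).

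Of the 37 gene lists, 8 passed camera's threshold as higher and 5 as lower in Tsc1-/-. None passed with an estimated correlation, where 6 had an unadjusted p under 0.05, while fry passed 11 and the exact permutation test of the list mean 8. As many lists passed camera's threshold in 13 of 100 splits of the arrays into 4 and 5, the real split included. The other 12 all kept WT replicates 1 to 3 on one side, and splits that parted these 3 arrays gave at most 12 lists. Each list below is given with its permutation test.

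The cell cycle lists had the largest shifts. The mitosis list was higher by 0.65 (SE 0.16), and all 19 measured members had a positive difference. Of these, 7 rose, and 19 passed when adjusted over the list alone. Cdk1, the mitotic kinase, rose by 0.73 (SE 0.13), the kinesin Kif11 by 0.78 (SE 0.15), the spindle protein Nusap1 by 0.80 (SE 0.16) and the topoisomerase Top2a by 0.67 (SE 0.13). The S phase list was higher by 0.54 (SE 0.16), with all 18 members positive, 3 past the threshold and 15 when adjusted over the list alone. Those 3 were Mcm2, of the replicative helicase (0.81), Gins2 (0.77) and Rrm1, of ribonucleotide reductase (0.67). Both lists separated the genotypes completely (exact permutation, adjusted p = 0.0367), with camera's adjusted p = 0.212 for mitosis and 0.255 for S phase with an estimated correlation. The mitosis score of WT replicates 3 and 4 (8.09 and 8.17) lay nearer to the Tsc1-/- arrays (8.37 to 8.65) than that of WT replicates 1 and 2 (7.56 and 7.51).

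**Figure D2:**
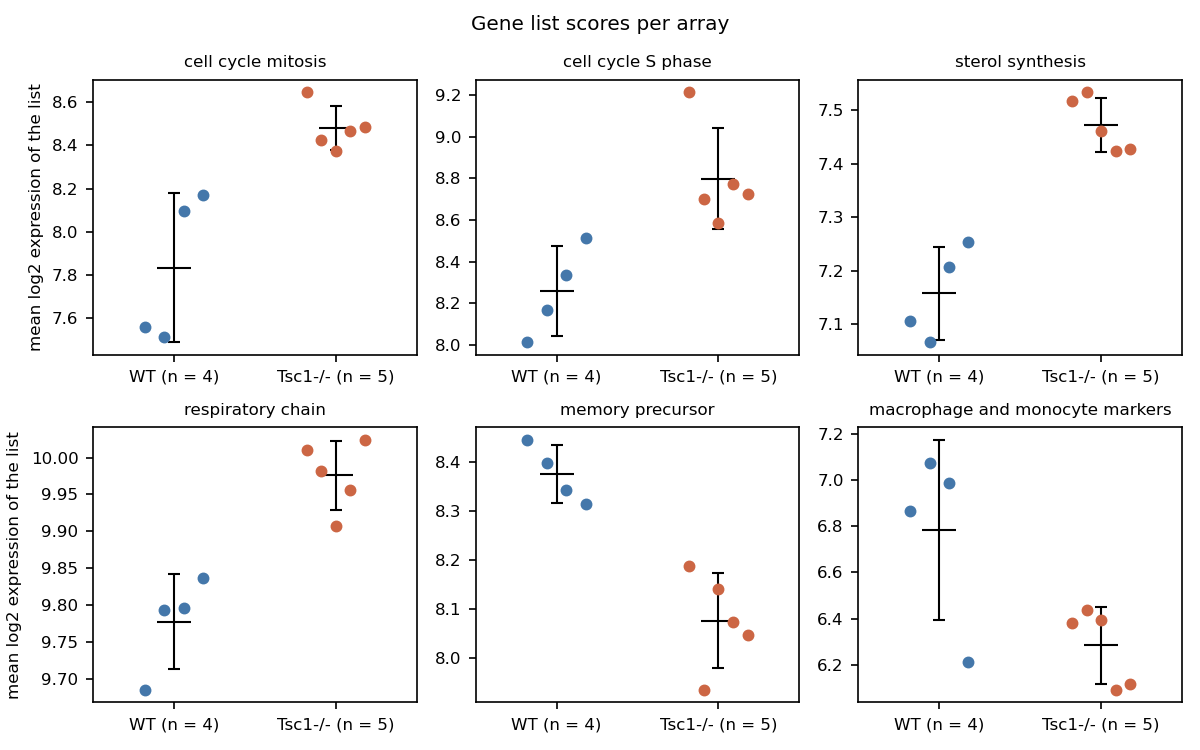
Mean log2 expression (vertical axes, which do not start at 0) of the genes of 6 lists on each array, for 4 WT and 5 Tsc1-/- samples. Points are arrays, horizontal marks group means and error bars 1 SD. The mitosis, S phase, sterol synthesis and respiratory chain scores were higher and the memory precursor score lower on every Tsc1-/- array, while the macrophage marker score of WT replicate 4 (6.21) lay within the Tsc1-/- range.

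Among metabolic lists, sterol synthesis was higher by 0.31 (SE 0.05), with 14 of 15 members positive. Of these, 5 rose and 7 passed when adjusted over the list alone: Cyp51, the lanosterol demethylase, rose by 0.57 (SE 0.08), Dhcr7, which makes cholesterol in the last step, by 0.39 (SE 0.08), Insig1, a sterol-sensing regulator, by 0.52 (SE 0.11), Fdps by 0.59 and Idi1 by 0.90. The respiratory chain list was higher by 0.20 (SE 0.04), with all 27 members positive, and by 0.11 without the trend on level and gene length, the smallest value over the settings. Of these, 2 rose, the complex I subunit Ndufs8 (0.39, SE 0.08) and cytochrome c, Cycs (0.36, SE 0.07), and 12 passed when adjusted over the list alone. Both lists separated the genotypes (exact permutation, adjusted p = 0.0367), and camera's adjusted p with an estimated correlation was 0.0793 for sterol synthesis and 0.212 for the respiratory chain.

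The amino acid stress response list, which holds targets of Atf4, was higher by 0.19 (SE 0.04), again with no overlap (exact permutation, adjusted p = 0.0367; camera, adjusted p = 0.212 with an estimated correlation). None of its 20 members passed by itself and 3 did when adjusted over the list alone. The aminoacyl-tRNA synthetase genes Wars and Gars differed by 0.36 and 0.31 (adjusted p = 0.0529 and 0.0719, limma). The unfolded protein response list was higher by 0.23 (SE 0.06), with all 16 members positive, none past the threshold and 7 when adjusted over the list alone (exact permutation, adjusted p = 0.0534; camera, adjusted p = 0.212 with an estimated correlation). Its member Sdf2l1 differed by 0.55 (adjusted p = 0.0567, limma) and Manf by 0.37 (adjusted p = 0.0750, limma).

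Glycolysis was higher as a list by 0.14 (SE 0.05; exact permutation, adjusted p = 0.0534; camera, adjusted p = 0.255 with an estimated correlation), with 16 of 18 members positive. Its call also ended with dim genes left out (0.12, adjusted p = 0.192, camera) and with the macrophage marker level as a covariate (0.13, adjusted p = 0.0688, camera). Aldoc, a dim aldolase, rose by 0.48 (SE 0.10), while Pdk1, the kinase that inhibits pyruvate dehydrogenase, fell by 0.50 (SE 0.11), and 2 rose and 1 fell when adjusted over the list alone. The other 16 did not pass, among them Ldha (0.20, adjusted p = 0.278), Hk2 (0.18, adjusted p = 0.594) and the glucose transporter Slc2a1 (0.10, 95% interval -0.07 to 0.27). Hif1a differed by 0.26 (adjusted p = 0.299) and Myc by -0.53 (adjusted p = 0.0750). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, differed by -0.09 (95% interval -0.36 to 0.17).

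Memory precursor genes were lower as a list by -0.30 (SE 0.06), with 14 of 16 members negative and no overlap between genotypes (exact permutation, adjusted p = 0.0367; camera, adjusted p = 0.138 with an estimated correlation). Slamf6 and Eomes fell, and 7 members passed as lower when adjusted over the list alone. Bcl2, the survival factor, differed by -0.51 (95% interval -0.91 to -0.10, adjusted p = 0.190) and Bcl6 by -0.46 (adjusted p = 0.166). Foxo1 differed by 0.02 (95% interval -0.15 to 0.20). Il7r and Tcf7 had no named probe set and were not analysed here.

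Cytotoxicity and cytokine genes were higher as a list by 0.17 (SE 0.06), with 13 of 20 members positive (exact permutation, adjusted p = 0.0979; camera, adjusted p = 0.255 with an estimated correlation). Its call ended with the macrophage marker level (0.11, adjusted p = 0.327, camera) or the B cell marker level (0.12, adjusted p = 0.194, camera) as a covariate. Gzmb, which encodes granzyme B, rose by 0.58 (SE 0.11), from 11.54 ± 0.17 to 12.12 ± 0.16 (SD, n = 4 and 5), and was the only member past the threshold; 7 rose and 1 fell when adjusted over the list alone. All Tsc1-/- mice, and no WT mice, carried the Granzyme B-cre transgene, so genotype and transgene go together for this and every other gene. An effect of cre itself cannot be told apart from loss of Tsc1 in any result here. Ifng differed by 0.21 (95% interval -0.08 to 0.50). The terminal effector list did not pass (0.17, SE 0.04; camera, adjusted p = 0.0677; exact permutation, adjusted p = 0.0534). Its member Il12rb2, a chain of the IL-12 receptor, rose by 0.74 (SE 0.12), and 3 rose and 1 fell when adjusted over the list alone. Klrg1, a surface marker of short-lived effectors, differed by 0.41 (95% interval 0.20 to 0.61, adjusted p = 0.0534), and Tbx21, the T-bet gene, by 0.00 (95% interval -0.20 to 0.20).

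Ribosomal proteins and elongation factors were lower as a list by -0.11 (SE 0.03), with 18 of 19 members negative and none past the threshold, also when adjusted over the list alone (exact permutation, adjusted p = 0.0367; camera, adjusted p = 0.330 with an estimated correlation), and the call ended with the macrophage marker level as a covariate (-0.07, adjusted p = 0.0780, camera). Eef1b2 differed by -0.21 and Eef2 by -0.19. Chemokine receptors and integrins shifted by -0.10 (SE 0.03), past the exact permutation test (adjusted p = 0.0367) and not past camera (adjusted p = 0.0936), with Cd44 at -0.36 and Itga4 at -0.26, neither past the threshold. Camera did pass this list with probe sets not joined (-0.19, adjusted p = 6.99e-07), dim genes left out (-0.11, adjusted p = 0.0223) and quantile normalization (-0.13, adjusted p = 0.0210).

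Markers of other spleen cells were also lower in Tsc1-/-, beside all of these groups. The macrophage and monocyte list differed by -0.50 (SE 0.19), the dendritic cell list by -0.37 (SE 0.17) and the B cell list by -0.33 (SE 0.15), each past camera and none past the exact permutation test (adjusted p = 0.128, 0.168 and 0.147), with camera's adjusted p = 0.255 for all 3 with an estimated correlation. No member of these lists passed by itself. C1qa differed by -0.96 (adjusted p = 0.0586, limma), Cd74 by -0.70, Cd22 by -0.63 and Csf1r by -0.47. The largest falls given above, Ear3 (-2.14) and the myeloid receptor gene Cd300ld (-1.21), are of genes outside these lists and did pass. So did Adgre4 (-1.11), Tifab (-0.94), Apoc2 (-0.75), Spic (-0.69), Apoe (-0.67), Plaur (-0.43) and Slamf9 (-0.41), which the naming rule left out. These were picked after their values were seen, and their relation to the macrophage score is given further below. The macrophage score was 6.86 to 7.07 in WT replicates 1 to 3, 6.21 in WT replicate 4 and 6.09 to 6.44 in Tsc1-/-. With that score as a covariate, limma called 0 genes higher and 0 lower (1772 at an unadjusted p under 0.05), while the median differences of the 166 and 53 genes were 0.46 and -0.48, against 0.49 and -0.51 without it. Camera with its preset correlation then passed 7 lists, with shifts of 0.42 (SE 0.21) for mitosis, 0.40 (SE 0.22) for S phase, 0.27 for sterol synthesis, 0.23 for the unfolded protein response, 0.16 for the respiratory chain, 0.15 for the amino acid stress response and -0.26 for memory precursors. At equal macrophage marker level the permutation p was 0.0789 for mitosis, 0.126 for S phase and 0.0244 for memory precursors. The other lists were not put to that permutation test, so camera's calls alone do not show that they hold at equal marker level. Glycolysis, cytotoxicity and cytokines, ribosomal proteins, and the dendritic and B cell markers no longer passed, and the macrophage list, as the covariate, was not counted.

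The other lists did not pass in the main fit. Positive mean shifts were those of p53 targets (0.14), lysosome and autophagy (0.11), mTOR pathway components (0.10), citric acid cycle (0.09), pro-apoptotic genes (0.07), pentose phosphate pathway (0.07), fatty acid oxidation (0.05), hypoxia response (0.03), fatty acid synthesis (0.01), ribosome biogenesis and Myc targets (0.01) and the type I interferon response (0.00). Of their members, Lamp2 and the desaturase Fads1 (0.53, SE 0.11) rose. Among those that did not pass were Cdkn1a (0.52), Rragc (0.42), Fas (0.41), Rheb (0.31) and Bak1 (0.31). Negative shifts were those of neutrophil markers (-0.30), erythroid markers (-0.21), NK cell markers (-0.20), handling stress genes (-0.15), FoxO targets (-0.10), cytokine receptors (-0.10), platelet markers (-0.06), Y-linked genes with Xist (-0.04), T cell receptor signalling (-0.03), CD4 and regulatory T cell markers (-0.03) and inhibitory receptors (-0.01), whose members Btla and Entpd1 differed by -0.50 and 0.35 without passing. Fcer1g and Tyrobp, of the NK cell list, differed by -0.95 (adjusted p = 0.0680, limma) and -0.77 (adjusted p = 0.178, limma). With the macrophage marker level as a covariate, Tyrobp was 0.084 and the NK cell list 0.092. These values therefore do not show a difference in NK cells. Of the handling stress genes, Fosb differed by -0.84 (adjusted p = 0.0718) and Fos by -0.73 (adjusted p = 0.140), and 2 members fell when adjusted over the list alone. Leaving out single arrays moved the neutrophil shift between -0.55 (without Tsc1-/- replicate 2) and -0.08 (Tsc1-/- replicate 5), the erythroid shift between -0.37 (Tsc1-/- replicate 2) and -0.13 (Tsc1-/- replicate 5), the NK cell shift between -0.31 (WT replicate 4) and -0.12 (WT replicate 2) and the handling stress shift between -0.31 (WT replicate 3) and 0.01 (Tsc1-/- replicate 4). Over the same fits the FoxO shift lay between -0.12 and -0.05 and the fatty acid oxidation shift between 0.02 and 0.06. Camera passed the neutrophil, erythroid and NK cell lists without Tsc1-/- replicate 2, the NK cell list also without WT replicate 4, and handling stress genes without Tsc1-/- replicate 3 (-0.28). The NK cell list also passed with dim genes left out (-0.30), quantile normalization (-0.24) and median centring (-0.17). With the replicate block and without the trend on level and gene length, camera passed NK cell markers (-0.22 and -0.26) and handling stress genes (-0.21 and -0.23).

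**Figure D3:**
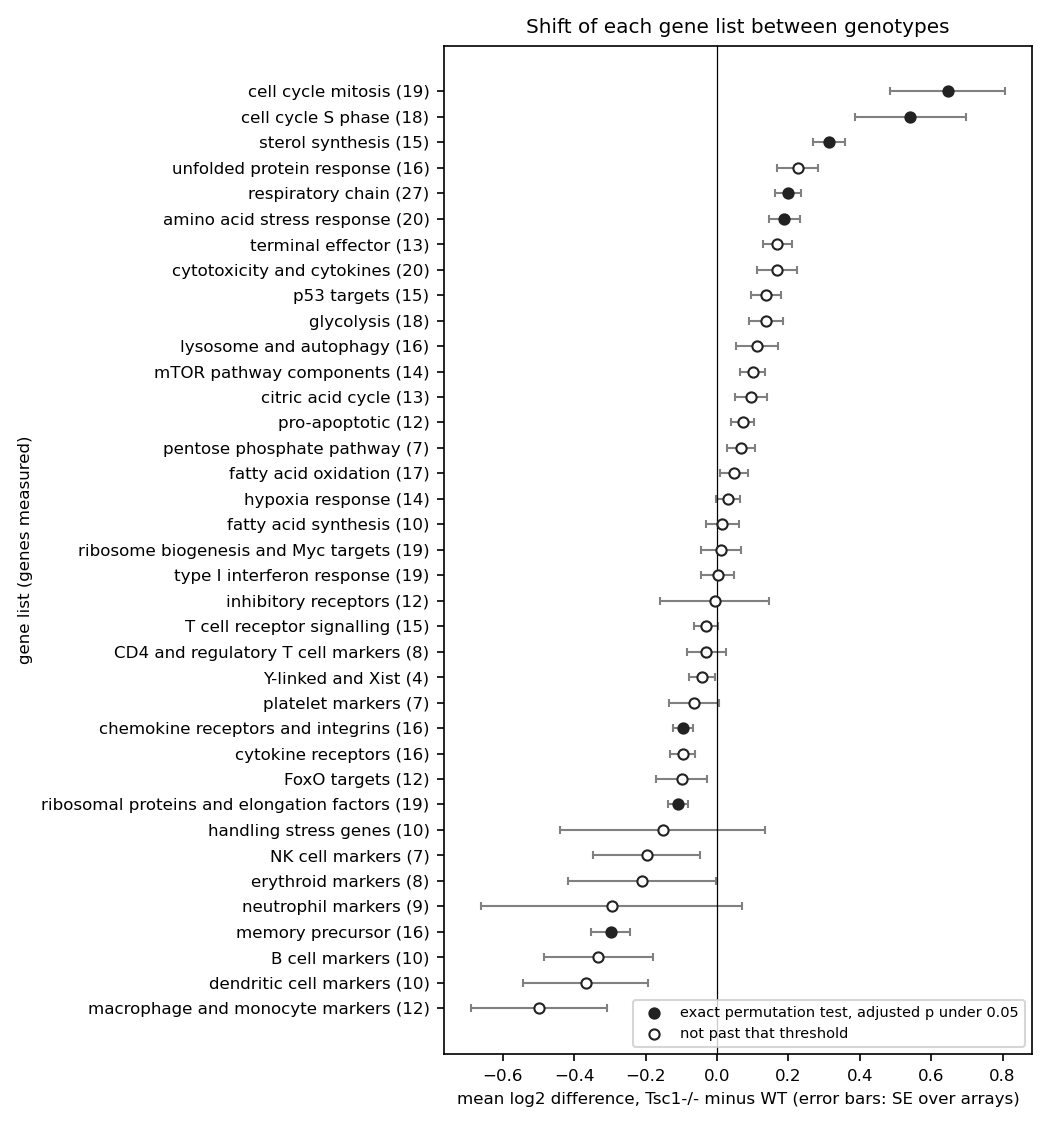
Mean log2 difference (Tsc1-/- minus WT, horizontal axis) of each of the 37 gene lists, with the number of genes measured in parentheses and error bars of 1 SE over arrays (4 WT, 5 Tsc1-/-). Filled points mark the 8 lists past the exact permutation test after adjustment. The mitosis list has the largest positive shift (0.65), while the macrophage and monocyte list, which did not pass that test, has the largest negative one (-0.50).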

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

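The splits of the arrays, the comparison with T cell receptor genes, the removal of the trend on level and gene length, the fit at equal macrophage marker level and the relation between macrophage and B cell scores were tests chosen after the results were seen. The relation between the mitosis and memory scores and the relation of the lower genes to the macrophage score were set down beforehand.

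Grouping of the arrays was tested with 100 of the 126 splits of the 9 arrays into 4 and 5, the real one included. As many higher genes came from 1 of the 100, the real split (166 genes, at most 0 in any other), and as many lower genes also from 1 of 100 (53, at most 1 in any other). Random regrouping of the arrays thus seldom gave such counts. The test was chosen after the results were seen, and it cannot tell genotype from a difference between samples that follows it. As many gene lists past camera's threshold came from 13 of 100 splits (13 lists, up to 17 in another), so chance cannot be excluded for the number of lists. The other 12 of these splits all kept WT replicates 1 to 3 on one side, as the real one does, a grouping noticed after the counts were seen, while the 86 splits that parted them gave at most 12 lists. Such a pattern can come from a structure of the samples that genotype shares in part. These splits also keep most WT arrays on one side, so an effect of genotype could raise their counts too.

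The cell cycle lists were higher in Tsc1-/- cells by 0.65 (mitosis) and 0.54 (S phase), over WT arrays that spread widely (mitosis SD 0.35 in WT and 0.10 in Tsc1-/-). If RNA of other cells had diluted T cell RNA in the WT sorts, T cell receptor genes would be higher in Tsc1-/- by about as much, but their list differed by -0.030 (SE 0.03). Without the trend on level and gene length the mitosis shift was 0.59 (SE 0.16), which argues against that trend as its whole source. At equal macrophage marker level the shifts were 0.42 (SE 0.21, permutation p = 0.0789) for mitosis and 0.40 (SE 0.22, permutation p = 0.126) for S phase, so a difference between samples that goes with those markers cannot be told apart from genotype, with which the marker level itself differs. An effect of genotype stays open, and neither its mechanism nor the stage of the response of each sample was tested.

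The memory precursor list was lower in Tsc1-/- cells by -0.30 (SE 0.06). At equal macrophage marker level the shift was -0.26 (SE 0.08, permutation p = 0.0244), and without the trend on level and gene length it was -0.32 (SE 0.06). That trend could therefore not account for the whole of it. The macrophage score differs between genotypes and may not follow every other cell type, so a smaller share of other cells is not excluded. Whether a larger share of dividing cells lowers the list cannot be told apart from an effect of genotype on these genes: within genotypes the mitosis and memory scores had r = -0.26 over 9 arrays (permutation p = 0.390, also after adjustment over the 2 relations computed; Spearman's rho = -0.40, permutation p = 0.293), and r = -0.09 without the 2 arrays farthest from the median. An effect of genotype stays open, and its mechanism was not tested.

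Markers of macrophages, dendritic cells and B cells were lower in Tsc1-/- sorts, with Cd74 at 10.92 in WT and 10.22 in Tsc1-/-, C1qa at 7.08 and 6.12 and Cd22 at 6.58 and 5.96. Within genotypes the macrophage and B cell scores went together (r = 0.91 over 9 arrays, permutation p = 0.00139, adjusted p = 0.00278; Spearman's rho = 0.88, permutation p = 0.00347, adjusted p = 0.00694; r = 0.87 without the 2 arrays farthest from the median), and without the trend on level and gene length the macrophage shift was -0.51 (SE 0.19). This is consistent with fewer other cells passing the Tsc1-/- sorts, although the gate on OVA+ CD8+ cells should remove them, and of the 3 lists' genes 1, the dendritic cell marker Ccr9, is also in the list of chemokine receptors. For the 53 lower genes the same explanation was not decided: their median within-genotype correlation with the macrophage score was 0.11, between the median (0.01) and the 95th percentile (0.13) of 10000 random lists of like mean level. Of these 53 genes, 5 had a correlation above 0.7, chosen here after their values were seen: Apoe, Apoc2, Tifab, Pisd and 4933407I05Rik, against 3.82% of all genes. Adgre4 (0.61), Plaur (0.60), Ear3 (0.54), Spic (0.39), Cd300ld (0.36) and Slamf9 (0.31) were also positive. Others were negative, among them Slamf6 (-0.10), Gpr183 (-0.54) and Lyst (-0.53).

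One array stood apart from the rest of its genotype in 21 of 286 groups tested, where chance gives about 14.3. WT replicate 4 lay below the other WT arrays in Ace (7.05 against 7.51 to 7.59), Entpd1 (7.38 against 7.67 to 7.72), Csf1r (6.07 against 6.49 to 6.56), C1qa (6.16 against 7.32 to 7.52) and Cd74 (10.06 against 11.11 to 11.26), and above them in Gars (9.39 against 9.21 to 9.24) and Hif1a (8.47 against 8.09 to 8.12). Tsc1-/- replicate 1 lay below its group in Serpinb1a (6.65 against 7.40 to 7.66), Lamp2 (7.58 against 8.22 to 8.43), Fyn (10.23 against 10.31 to 10.33) and Il6ra (6.86 against 7.42 to 7.63), and above it in Fh1 (8.66 against 8.12 to 8.27), Gzmb (12.40 against 12.00 to 12.11) and Mmp9 (5.79 against 5.61 to 5.64). In WT replicate 1, Cd300ld (6.86 against 6.33 to 6.36), Eomes (8.91 against 8.59 to 8.62) and Slc2a1 (9.86 against 9.72 to 9.73) were high, and in WT replicate 3 Ctla2a (11.72 against 11.87 to 11.88) was low. AA467197 was low in Tsc1-/- replicate 4 (9.30 against 9.84 to 9.90), and Trat1 (6.34 against 5.90 to 5.94) and the citric acid cycle score (9.04 against 8.90 to 8.94) were high in Tsc1-/- replicate 5.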

How the results depend on the processing

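The settings with a marker covariate, without the trend on level and gene length, and without 2 arrays together were chosen after seeing the data. In all settings those of the called genes that were tested kept their direction, except 1 higher gene with the mean of probe sets. For called genes whose genotypes did not overlap, leaving out arrays could not change the direction. The counts, 166 higher and 53 lower, moved as follows. They were 542 and 140 with dim genes left out, 43 and 34 with quantile normalization, 338 and 63 with median centring, 509 and 171 with a variance trend and robust estimation, 340 and 125 with array weights, 54 and 16 at 1.5-fold or more, 529 and 209 at an adjusted p under 0.1, 55 higher without the trend on level and gene length, and 145 lower without WT replicate 4 and Tsc1-/- replicate 1. Leaving out single arrays gave 1 to 297 higher and 1 to 159 lower genes; fewer arrays give larger adjusted p-values, but why WT replicate 4 acts the other way was not tested. With the macrophage marker covariate, limma called 0 and 0 genes (1772 at an unadjusted p under 0.05) and camera 7 lists, without glycolysis, cytotoxicity and cytokines, ribosomal proteins and the markers of dendritic cells and B cells (macrophage markers, as the covariate, untested); with the B cell marker covariate limma called 0 and 0 (1880 at an unadjusted p under 0.05), and camera no longer passed cytotoxicity and cytokines or the macrophage markers (B cell markers untested). With dim genes left out glycolysis did not pass, while chemokine receptors and integrins (-0.11), cytokine receptors (-0.08) and NK cell markers (-0.30) did. Quantile normalization added FoxO targets (-0.16), chemokine receptors and integrins (-0.13), cytokine receptors (-0.14) and NK cell markers (-0.24). Median centring added citric acid cycle (0.12) and NK cell markers (-0.17). The p53 targets were added with the mean of probe sets (0.14), probe sets not joined (0.15) and array weights (0.15). Camera gained lists without single arrays: cytokine receptors (-0.10) without WT replicate 2; chemokine receptors and integrins (-0.12) without WT replicate 3; citric acid cycle (0.13) and NK cell markers (-0.31) without WT replicate 4; citric acid cycle (0.10), lysosome and autophagy (0.15), terminal effector (0.19), p53 targets (0.16) and cytokine receptors (-0.12) without Tsc1-/- replicate 1; citric acid cycle (0.11), neutrophil (-0.55), NK cell (-0.27) and erythroid markers (-0.37) without Tsc1-/- replicate 2; and handling stress genes (-0.28) without Tsc1-/- replicate 3. Both covariates differ between genotypes, which widens the error of the genotype term. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05, and 11 by fry). In each fit without 1 array all 13 lists passed again. Among lists that still passed, shifts fell over 1.5 times for the respiratory chain (0.11) and the unfolded protein response (0.14) without the trend, for mitosis with the macrophage covariate (0.42) and for ribosomal proteins with probe sets not joined (-0.07). Tsc1 was past the threshold only with dim genes left out (-0.26), where fewer genes are tested, and its adjusted p ranged from 0.0483 to 0.556. The replicate numbers are shared by the genotypes, but same-numbered arrays did not deviate together (correlations -0.10, 0.09, -0.07 and 0.02), and only replicate 2 correlated best with its own number, so the numbers do not pair the samples. With the replicate block limma called 0 and 0 genes (2354 at an unadjusted p under 0.05), Tbx21 was 0.035 and the interferon list -0.029. No WT array shares the number of Tsc1-/- replicate 5, so the block takes that array out of the comparison. These 2 estimates equal those without Tsc1-/- replicate 5, a setting that by itself left 1 higher and 1 lower gene. The block is therefore not a separate check from that setting. Of the other results that reversed in some setting, B cell markers had passed and the rest had not. Under the mean of probe sets they were Uty (-0.0059), fatty acid synthesis (-0.0078), inhibitory receptors (0.016) and Myc targets (-0.0050); with probe sets not joined, fatty acid synthesis (-0.015) and inhibitory receptors (0.055); with dim genes left out, inhibitory receptors (0.010), Myc targets (-0.0083) and CD4 markers (0.049); with quantile normalization, Foxo1 (-0.031), fatty acid synthesis (-0.0062), interferon (-0.023) and Myc targets (-0.037). Median centring gave Tbx21 0.028 and inhibitory receptors 0.022, and array weights gave Tbx21 0.018 and Myc targets -0.0088. The macrophage covariate gave Tyrobp 0.084, Car2 0.032, inhibitory receptors 0.043, B cell 0.030, neutrophil 0.022, NK cell 0.092 and erythroid markers 0.065. The B cell covariate gave Car2 0.022, Alas2 0.10, Tbx21 0.046, inhibitory receptors 0.016, interferon -0.015, neutrophil 0.24, NK cell 0.039 and erythroid markers 0.15. Without the trend, the pentose phosphate list was -0.012, interferon -0.035 and Myc targets -0.054. Without the 2 arrays, Uty was -0.040, Tbx21 0.060, Foxo1 -0.024, Cpt1a 0.035, fatty acid synthesis -0.0040, interferon -0.0079 and Myc targets -0.024. Without single arrays, Tbx21 lay between -0.052 and 0.035, Foxo1 between -0.0090 and 0.060, Uty between -0.00069 and 0.11, inhibitory receptors between -0.13 and 0.065, interferon between -0.029 and 0.021, Myc targets between -0.034 and 0.032, fatty acid synthesis between -0.027 and 0.040 and handling stress genes between -0.31 and 0.015. Over all settings, 445 single-gene values lost and 123 gained the threshold against 1808 that stayed on their side, and 20 list values lost and 48 gained it against 711; the cause was not tested.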

Other observations

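Families of genes beyond the fixed lists were examined after the results of single genes were seen. Proteasome subunits were higher in Tsc1-/- cells as a family by 0.24 (SE 0.03), with 36 of 37 genes positive and 3 past the threshold (Psmb6 0.43, Psmd14 0.43 and Psma1 0.35, named after their values were seen). Mitochondrial ribosome subunits were higher by 0.19 (SE 0.03), with 66 of 73 positive and 4 past the threshold (Mrpl38 0.44, Mrps21 0.40, Mrps14 0.39 and Mrpl16 0.37, also named after their values were seen). The cytoplasmic ribosome differed the other way, by -0.07 (SE 0.01), with 56 of 63 genes negative and none past the threshold. Subunits of RNA polymerase II (0.18, SE 0.04), the anaphase promoting complex (0.18, SE 0.03) and the kinesins (0.14, SE 0.03) were higher, while the 3 metallothionein genes went both ways, with Mt1 up and the other 2 negative. Each of the proteasome, both ribosomes, the polymerase, the anaphase promoting complex and the kinesins had an exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0132 over the 10 families computed. Without the trend on level and gene length the polymerase shift fell to 0.09 (SE 0.03, exact permutation p = 0.0397) and that of the anaphase promoting complex to 0.12 (SE 0.02, exact permutation p = 0.0159), while the kinesins (0.15, SE 0.04) and the cytoplasmic ribosome (-0.10, SE 0.01) kept the smallest p.

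The tests of 4 families were set down before the family results were seen, but after those of single genes on the same arrays. Called members stayed in the proteasome and mitochondrial ribosome families, so the rise of these families in part restates those calls. The proteasome was higher as a family with and without the trend on level and gene length (0.17 without it, SE 0.02, exact permutation p = 0.00794), and so was the mitochondrial ribosome (0.11, SE 0.02, exact permutation p = 0.00794). Both families keep their direction there, although removing the trend lowered both shifts, so part of each may come from the brighter level of these genes. The chaperonin subunits did not rise as a family (0.04, SE 0.03, exact permutation p = 0.127, and p = 0.317 without the trend), nor did the 295 zinc finger genes of the Zfp series fall (-0.01, SE 0.02, exact permutation p = 0.516 without the trend). With quantile normalization or median centring of the deposited values the families kept their directions, except the chaperonin (-0.01 after quantile normalization) and the Zfp series (0.02 after median centring). Over genes, the log2 difference had a Spearman correlation of 0.21 with mean level and -0.08 with gene length, and the median difference was -0.02 in the dimmest and 0.06 in the brightest of 8 equal bins of level; genes are not independent replicates.

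Probe sets without a gene name here also held differences. When all 45037 probe sets were tested together with limma, 10 of the 15588 unnamed ones were higher and 19 lower in Tsc1-/-, against 59 higher and 20 lower among the listed ones.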
